A study of Solanum tuberosum with 24 samples.

How the data were processed

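Potato leaves of 4 genotypes (CARDINAL, DESIEE, CLON 37FB and MIJE) were profiled by RNA sequencing under irrigation and drought, in 24 samples that form 8 groups of 3. According to the labels, RNA of the third unfolded leaf was made into libraries with a TruSeq RNA kit that selects polyadenylated RNA, and sequenced on a HiSeq 2500 as paired reads of 125 bp. Strand specificity was not stated. The submitters name bcl2fastq 1.8.4, TopHat2 2.0.9, SAMtools, Cufflinks 2.1.1 and Cuffdiff as their processing tools. Their settings and the genome build are not given in the sources used here.

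The authors deposited 1 table per genotype. Each table holds the genes that the authors' test called between the control and the treatment condition, which were read as irrigation and drought. Its columns are Cuffdiff's: a gene identifier and locus, 1 FPKM value per condition with the replicates pooled, the log2 ratio of treatment over control, a test statistic, a p-value and a q-value. The FPKM values, log2 ratios and test statistics, written with decimal commas, were normalized by the authors within each table, so a level is compared across tables only where that is said. All unit columns of the deposited tables are of this other kind, neither counts nor values per sample. Genes without a call and values per sample were not analysed here. The depth per sample is therefore unknown, and no interval that needs counts was computed for an expression value. Some loci of chromosome 1 had values rounded to whole numbers, 1 in CARDINAL, 24 in DESIEE, 0 in CLON 37FB and 9 in MIJE. Their FPKM values were taken from the second pair of value columns, which holds values to 0.01 FPKM. The check that both pairs match elsewhere had a tolerance of 0.01. Log2 ratios of the rounded loci were recomputed and are less exact at low FPKM. Entries that name several genes were kept (0, 4, 6 and 4 in the same order). Genes listed at 0 FPKM in one condition count towards the numbers of calls and carry no fold change.

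A gene was called at the authors' q of at most 0.05 with no minimum fold change, and the numbers higher and lower under drought were counted, with 95% Wilson intervals of the share that was higher. The number of loci the authors tested was recovered from q, rank and p under the Benjamini-Hochberg formula. It came to 18844 in CARDINAL, 19013 in DESIEE, 19490 in CLON 37FB and 19119 in MIJE. For each of the 6 pairs of genotypes the genes called in both were counted, and Fisher's exact test (two-sided) compared direction in one with direction in the other, adjusted over the 6 pairs by the Benjamini-Hochberg method. The number expected of independent lists is the product of both numbers of calls over the smaller number of loci tested. Genes that respond are measured better at high expression, so an excess over that number does not show a shared response by itself.

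The difference of the drought response between genotypes was tested per gene called in both tables. The difference of both log2 fold changes was divided by the root of the summed squared standard errors, two-sided with a normal distribution, and adjusted by the Benjamini-Hochberg method within each pair. Each standard error was the log2 fold change over the deposited test statistic. That choice had been tied, before the data were examined, to a match of the deposited p with the normal p of the statistic, and the match was absent: the normal p was the larger in 74 of 79 genes in CARDINAL, 1705 of 1815 in DESIEE, 1076 of 1138 in CLON 37FB and 917 of 972 in MIJE. It was kept because it gives the larger errors in most genes, and standard errors from the deposited p-value are the alternative. Genes with a rounded statistic were left out of this test.

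Gene lists were 37 sets fixed by words in the gene descriptions of the tables. Since the tables hold called genes alone, each list with at least 5 called members was tested by Fisher's exact test (two-sided) for the share of higher members against all other called genes of that genotype. Adjustment ran over the 80 tests of lists and genotypes. A count adjusted over the list alone was not possible, because members without a call are not in the tables. Words also catch some unintended descriptions: the list of dividing tissue takes in proteins of membrane recycling, that of cysteine proteases takes in their inhibitors, and that of pathogenesis-related proteins takes in an endoglucanase inhibitor and leaves out the beta-1,3-glucanase named in the report. The list of ribosomal proteins takes in a kinase of a ribosomal protein. Neighbouring copies of a family can share reads and are not independent, which the list tests ignore. Among the genes called in CLON 37FB and MIJE, 9 lists were further tested for opposite directions, a test chosen after the directions had been seen. The comparison tables, the lists, the thresholds and the rule for named genes were chosen before the data were examined.

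Named genes followed a rule. Per genotype it took the 6 largest rises and the 6 largest falls among called genes with a finite fold change, at least 5 FPKM in the higher condition and a description that names a protein. Per described list it took up to 3 called members by the size of the change, and over genotypes up to 12 genes called in the most genotypes. Values of a named gene in the other genotypes are given for some genes only, so an absent value does not mean an absent call. Function clauses are background knowledge on the described protein.

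The alternatives were a q threshold of 0.01, an absolute log2 fold change of at least 1 or 2, minimum values of 1 or 5 FPKM, leaving out genes listed at 0 or entries with several names, a fold change recomputed with 1 FPKM added, and standard errors from the deposited p-value. For the lists they also included counting each distinct description once. Counting neighbours within 200 kb once and leaving out proteins usually encoded in the plastid genome were added after the data had been seen.

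The steps were tested on simulated data. With 19000 loci the recovered number of loci tested was 19000 in each of the 4 tables. With 50 genes given a log2 difference of 4, the difference test recovered 43 in the pair of CLON 37FB and MIJE, 39 in that of DESIEE and CLON 37FB and 49 in that of DESIEE and MIJE, and called 2 genes without a difference in each pair. Over 200 simulated sets of directions the changed list was called in 200 sets for DESIEE, 200 for CLON 37FB and 197 for MIJE, and any other list in 10, 8 and 7 sets. The recovered number of loci only inverts the formula that made the simulated q-values. Simulated differences had normal errors and no filter on calls, and simulated directions were drawn independently per gene. The real tables differ in these points, so the rates check the computation and are not error rates of the real tests. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.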

Results

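Leaf transcriptomes of 4 potato genotypes, named CARDINAL, DESIEE, CLON 37FB and MIJE in the labels, were sequenced from plants grown with irrigation or under drought. The series was set up to compare contrasting genotypes in their response to water shortage. Each genotype contributed 3 irrigated and 3 drought samples of the third unfolded leaf, 24 samples in 8 groups. The authors' deposited tables, one per genotype, listed the genes that their own test called between drought and irrigation, with one pooled FPKM value per condition, which counts sequenced fragments per length of transcript and per size of library. Values of single samples and read totals were not analysed here, so no spread of this work's own stands beside a value, the depth per sample is unknown, and the replicate error enters only through the authors' q-value. The labels number the samples of a group but do not say whether they came from separate plants, so those q-values measure the spread between these samples, which may be technical. Locus coordinates are printed as the authors' deposited tables give them, span exons and introns alike, and belong to a genome build that is not given in the sources used here. Gene functions are the descriptions that these tables attach to each identifier.

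The 4 genotypes differed widely in the number of genes called at q of at most 0.05. The authors' deposited tables held 1867 genes for DESIEE, 1179 for CLON 37FB, 1010 for MIJE and 101 for CARDINAL. The largest p of the authors' test among these calls was 0.0049, 0.003, 0.0026 and 0.00025 in the same order. Their smallest absolute log2 fold change, where finite, was 0.73, 1.01, 0.90 and 1.25. The counts therefore do not rank the genotypes by size of response. Direction differed as well. In DESIEE 763 genes were higher and 1104 lower under drought, and in CLON 37FB 332 were higher and 847 lower. In MIJE 642 were higher and 368 lower, and in CARDINAL 56 were higher and 45 lower. The share of called genes that were higher was 28.2% in CLON 37FB (95% Wilson interval 25.7 to 30.8) and 63.6% in MIJE (60.6 to 66.5), which covers counting error only.

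**Figure D1:**
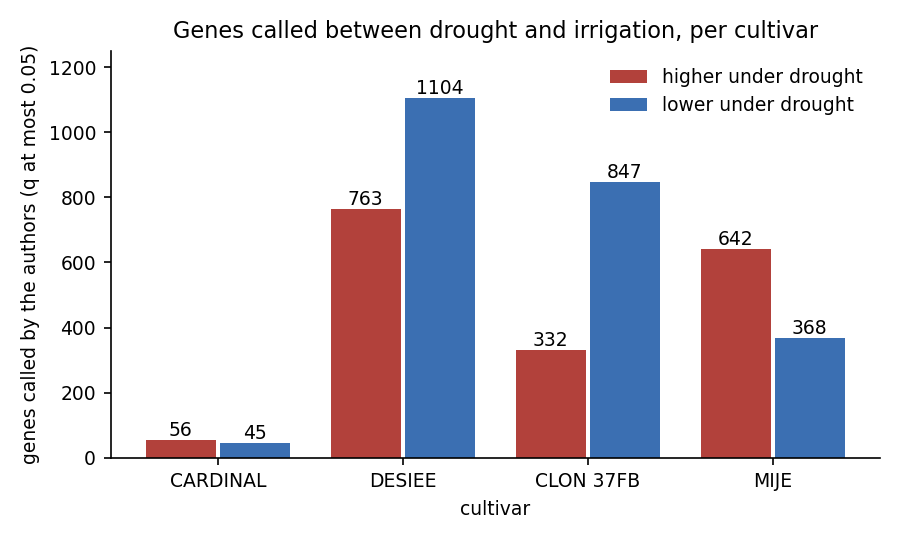
Number of genes (vertical axis) that the authors called between drought and irrigation at q of at most 0.05 in each cultivar (horizontal axis), with red bars for genes higher and blue bars for genes lower under drought. CARDINAL shows 56 and 45 genes, and the bars of the other cultivars lie between 332 and 1104.

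In CARDINAL, among described genes reaching 5 FPKM and above 0 in both conditions, the rise was steepest for a stay-green 2 gene, whose relatives act in chlorophyll degradation during senescence (Sotub12g024750, chromosome 12, 61017559 to 61020249). The authors' deposited table gave it 1.92 FPKM under irrigation and 91.8 FPKM under drought, at q = 0.0135. A UDP-glucosyltransferase (Sotub09g026370) rose by a log2 fold change of 5.08 and GH3.8, an auxin-conjugating enzyme (Sotub07g026480), by 4.48 in that deposited table. An expansin-like gene, of a family that loosens cell walls (Sotub06g021010), went from 10.2 to 143.6 FPKM, and a glyoxalase-type dioxygenase (Sotub03g029970) from 7.64 to 99.7 FPKM, in the authors' deposited table. A trehalose-phosphate synthase (Sotub07g005290), with a log2 fold change of 2.46, and a hydroxycinnamoyl transferase (Sotub02g031660), with 3.12, were also higher there. Desiccation-related genes were represented by dehydrin DHN1 (Sotub02g027970, log2 fold change 1.25, q = 0.0466) and a late embryogenesis abundant (LEA) protein (Sotub09g022810, 1.42) in the authors' deposited table.

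In the authors' deposited table an NBS-LRR resistance gene (Sotub04g012680, chromosome 4, 8167558 to 8170111) went from 7.16 to 0.445 FPKM and a second one (Sotub07g023470) from 133.7 to 12.8 FPKM. PR-1, a secreted pathogenesis-related protein (Sotub09g006080), fell from 43.5 to 5.55 FPKM, and a cytosol aminopeptidase (Sotub12g007850) from 11.4 to 0.779 FPKM, in that deposited table. Of 3 called proteinase inhibitors, 2 of the Kunitz type fell (Sotub03g012330, log2 fold change -2.19, and Sotub03g015820, -2.36) and 1 rose (Sotub03g016090, 3.34) in the authors' deposited table. An ammonium transporter (Sotub04g019200) had a log2 fold change of -1.91 in the same deposited table. All 5 called members of the list of photosynthetic light reactions were higher, against 53.1% of the other called genes (Fisher's exact test, two-sided, adjusted p = 0.18 over 80 list tests). Of these 5 members 3 were described as proteins usually encoded in the plastid genome, which leaves 2 others, both higher and too few for a test. Of the called genes in CARDINAL 21 were listed at 0 FPKM in one condition, 5 under irrigation and 16 under drought.

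Heat shock proteins, which keep other proteins folded, were mostly higher among the called genes of DESIEE. Of 39 called heat shock proteins and chaperones in the authors' deposited table, 35 were higher and 4 lower, 89.7% higher against 39.8% of the other called genes (Fisher's exact test, adjusted p = 1.5e-08). A dnaJ 11 chaperone (Sotub04g034910, chromosome 4, 65424367 to 65424838) went from 7.61 to 197.8 FPKM, a class I heat shock protein (Sotub06g032320) from 4.73 to 81.6 FPKM and a further heat shock protein (Sotub03g016820) from 10.97 to 142.4 FPKM in that deposited table. All 5 called heat stress transcription factors, the activators of those genes, were higher, with adjusted exact p = 0.065. Of 5 called LEA, dehydrin and ASR proteins 4 were higher and 1 lower (adjusted exact p = 0.35). TAS14, a dehydrin induced by abscisic acid (Sotub02g027980), rose from 218.0 to 1455 FPKM and an LEA protein (Sotub06g007530) fell from 247.2 to 57.3 FPKM in the authors' deposited table. A homeobox leucine zipper gene (Sotub08g027170) rose from 22.4 to 261.4 FPKM, and 15 of 23 called HD-Zip and bZIP factors were higher (adjusted exact p = 0.097). Legumain, a vacuolar processing protease (Sotub08g015300), went from 157.2 to 1533 FPKM, and the stay-green 2 gene Sotub12g024750 from 2.50 to 26.3 FPKM, in the authors' deposited table.

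WRKY regulators and single genes of sucrose and starch metabolism were among the falls in DESIEE. Sucrose synthase 4, which cleaves sucrose (Sotub12g008670, chromosome 12, 3087205 to 3091182), fell from 316.8 to 7.05 FPKM, a subunit of glucose-1-phosphate adenylyltransferase, the first committed step of starch synthesis (Sotub01g047210), from 1348 to 88.1 FPKM, and a starch branching enzyme (Sotub04g035850) from 370.6 to 93.9 FPKM in the authors' deposited table. Of the 14 called sucrose and starch genes 10 were lower (adjusted exact p = 0.65). All 14 called WRKY factors, regulators often tied to defence, were lower (adjusted exact p = 0.0082), with WRKY 3 (Sotub08g016820) at a log2 fold change of -2.55 and WRKY 6 (Sotub09g014330) at -1.78 in the authors' deposited table. Among phenylpropanoid and flavonoid genes 16 of 19 were lower (adjusted exact p = 0.12). A hydroxycinnamoyl transferase (Sotub05g025320) fell from 43.6 to 0.992 FPKM and chalcone isomerase (Sotub05g006820) from 349.6 to 58.4 FPKM in the authors' deposited table, while another hydroxycinnamoyl transferase (Sotub02g031660) rose from 0.133 to 11.5 FPKM. Cell wall genes were lower in 33 of 44 cases (adjusted exact p = 0.12), including a fasciclin-like arabinogalactan protein (Sotub10g005630, log2 fold change -3.30 in the deposited table). Genes of dividing tissue were lower in 21 of 28 cases (adjusted exact p = 0.27), histone H4 (Sotub04g010230) with -2.39 and Cdc6, a DNA replication licensing factor (Sotub06g032620), with -3.04 in the authors' deposited table.

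Among photosynthetic light reaction genes of DESIEE 8 of 9 were higher (adjusted exact p = 0.032), and among genes of lipid transfer, wax and cutin, the materials of the leaf surface, 15 of 21 (adjusted exact p = 0.041). Under 6 alternative settings the adjusted exact p of the former ran from 0.036 to 0.39 and that of the latter from 0.034 to 0.33. The light reaction call ended under 5 of the 6 and the lipid transfer call under 4, both at a q threshold of 0.01, with an absolute log2 fold change of at least 1, with each distinct description counted once and with neighbours counted once. Of the 5 called DESIEE genes described as proteins usually encoded in the plastid genome 2 were higher and 3 lower, and the light reaction list without its plastid-type members held 6 higher and 1 lower (adjusted exact p = 0.10). A GDSL lipase (Sotub02g018120) with a log2 fold change of 3.69 and a lipid transfer protein (Sotub10g010800) with 2.03 were among the rises in the authors' deposited table.

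Among the called genes of CLON 37FB, HD-Zip and bZIP factors and heat stress transcription factors were mostly higher, while most of all calls were falls. Of 18 called HD-Zip and bZIP factors 17 were higher, 94.4% against 27.1% of the other called genes (Fisher's exact test, adjusted p = 1.2e-07). The homeobox leucine zipper gene Sotub01g033820 (chromosome 1, 82689134 to 82689974) went from 5.35 to 152.6 FPKM, its relative Sotub08g027170 from 9.20 to 126.1 FPKM and a bZIP factor (Sotub04g031780) from 29.9 to 309.2 FPKM in the authors' deposited table. All 7 called heat stress transcription factors were higher (adjusted exact p = 0.0021), with A-6b (Sotub09g020500) at a log2 fold change of 4.76 and A3 (Sotub07g011590) at 4.02 in the authors' deposited table. A protein phosphatase 2C of the integrin-linked kinase-associated type (Sotub06g016130) rose by 5.32 on the log2 scale, an alpha-galactosidase (Sotub02g036380) by 5.22 and the seed protein SBP65 (Sotub10g008470) by 5.82 in that deposited table. 9-cis-epoxycarotenoid dioxygenase, the rate-limiting enzyme of abscisic acid synthesis (Sotub07g025690), went from 9.42 to 56.4 FPKM and TAS14 (Sotub02g027980) from 13.8 to 159.3 FPKM in the authors' deposited table. The log2 fold change of Sotub07g025690 was -0.93 in DESIEE and 1.62 in MIJE in the authors' deposited tables. That of another dioxygenase gene of this type (Sotub01g014090) was -3.61 in DESIEE and -1.76 in MIJE. A galactinol synthase, which feeds raffinose synthesis (Sotub02g028120), rose from 14.3 to 124.8 FPKM. A clock-associated gene annotated as ZGT (Sotub09g015170) went from 6.41 to 151.5 FPKM in the authors' deposited table.

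Of 19 called members of the list of photosynthetic light reactions in CLON 37FB 18 were higher, 94.7% against 27.1% of the other called genes (adjusted exact p = 5.0e-08). Chlorophyll a-b binding protein 1B (Sotub02g017340) went from 26.6 to 161.3 FPKM and protein 4 (Sotub06g026740) from 3.88 to 23.9 FPKM, while one copy of 3C (Sotub03g006060) fell from 102.6 to 17.3 FPKM, in the authors' deposited table. These genes lie in tandem copies that can share reads, so the split between copies is uncertain. Of the 19 members 4 were described as proteins usually encoded in the plastid genome, and without them 14 members were higher and 1 lower (adjusted exact p = 3.8e-06). Heat shock proteins were divided, 10 higher and 5 lower (adjusted exact p = 0.018), with a dnaJ chaperone (Sotub05g009640) at a log2 fold change of 2.96 and heat shock protein 22 (Sotub05g015330) at -4.23 in the authors' deposited table. At a q threshold of 0.01 the heat shock list held 3 higher and 4 lower members, with adjusted exact p = 0.65, and under the other 5 alternative settings its call was kept (lowest adjusted exact p = 0.0096).

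Of 25 called pathogenesis-related proteins in CLON 37FB 22 were lower and 3 higher (adjusted exact p = 0.20), and all 13 called proteinase inhibitors were lower (adjusted exact p = 0.11), in a genotype with 28.2% of all calls higher. PR-1b (Sotub09g006110, chromosome 9, 1449748 to 1450228) fell from 540.1 to 19.4 FPKM and PR-1 (Sotub09g006080) from 2345 to 175.1 FPKM in the authors' deposited table. Proteinase inhibitor 2 (Sotub03g012400), a wound-inducible inhibitor of digestive proteases, fell from 4098 to 155.8 FPKM and cysteine protease inhibitor 8 (Sotub03g016020) from 146.3 to 3.59 FPKM in that deposited table. Of 16 called antioxidant genes 15 were lower (adjusted exact p = 0.16), among them a glutathione S-transferase (Sotub09g012900) that went from 89.5 to 8.75 FPKM in the authors' deposited table. All 10 called WRKY factors were lower (adjusted exact p = 0.19), as were all 14 called genes of dividing tissue (adjusted exact p = 0.077), with 3 histone H3 genes (Sotub01g023070, Sotub01g026810 and Sotub10g009520) between -2.23 and -2.28 in the authors' deposited table. Phenylpropanoid genes were lower in 22 of 26 cases (adjusted exact p = 0.37), including chalcone synthase (Sotub09g027860), which fell from 138.2 to 13.7 FPKM in the deposited table.

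Of 44 called heat shock proteins and chaperones in MIJE 42 were higher and 2 lower, 95.5% against 62.1% of the other called genes (Fisher's exact test, adjusted p = 1.2e-05). A class IV heat shock protein (Sotub11g015500, chromosome 11, 13722083 to 13722677) went from 1.04 to 25.4 FPKM and heat shock protein 22 (Sotub05g015330) from 3.93 to 64.1 FPKM in the authors' deposited table. All 15 called light reaction genes were higher (adjusted exact p = 0.017), with chlorophyll a-b binding proteins Sotub01g042080 going from 161.8 to 502.9 FPKM and Sotub03g005990 from 289.7 to 862.0 FPKM in the authors' deposited table. Under 6 alternative settings this list's adjusted exact p ran from 0.015 to 0.25, and its call ended under 3 of them, with 0.064 when each distinct description counted once, 0.11 when neighbours within 200 kb counted once and 0.25 at a q threshold of 0.01. None of its 15 members was described as a protein usually encoded in the plastid genome, and 4 such genes called in MIJE outside the list divided into 2 higher and 2 lower. All 14 called antioxidant genes were higher (adjusted exact p = 0.025, and 0.0245 to 0.16 under 6 alternative settings, 2 of which ended the call), ascorbate peroxidase (Sotub09g006730) going from 40.4 to 133.5 FPKM in the authors' deposited table. Members of the list of ribosomal proteins were higher in 12 of 14 cases (adjusted exact p = 0.25). A lower member (Sotub02g013870) was described as a ribosomal protein S6 kinase, which is not itself a ribosomal protein.

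Of 21 called pathogenesis-related proteins in MIJE 19 were higher (adjusted exact p = 0.062) and of 12 called proteinase inhibitors 9 were higher (adjusted exact p = 0.75). A beta-1,3-glucanase (Sotub04g014510, chromosome 4, 14081940 to 14083196) went from 5.18 to 162.0 FPKM, an osmotin-like protein (Sotub08g026700) from 5.78 to 79.0 FPKM and polyphenol oxidase, an enzyme of trichomes and of browning (Sotub02g021500), from 2.63 to 62.9 FPKM in the authors' deposited table. A cytochrome P450 (Sotub04g025880) had a log2 fold change of 5.57 and a carboxyl methyltransferase (Sotub09g027900) of 4.38 there. The heat stress factor A3 gene Sotub07g011590 rose by 3.32 on the log2 scale, TAS14 (Sotub02g027980) by 2.58 and an LEA protein (Sotub03g029850) by 4.37 in the authors' deposited table.

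The falls in MIJE were led by a patatin-like phospholipase (Sotub08g006460, chromosome 8, 1434701 to 1440466), which went from 755.1 to 13.5 FPKM in the authors' deposited table. It is the single called MIJE member of the list of tuber storage proteins, which it entered by the words of its description. This membership does not show that tissue other than leaf was sampled. The log2 fold change was -4.58 for a beta-D-glucosidase (Sotub06g030420), -4.47 for endochitinase 4 (Sotub03g029630), -4.42 for a beta-carotene hydroxylase (Sotub03g015810) and -4.04 for the hydroxycinnamoyl transferase Sotub05g025320 in that deposited table. WRKY factors were lower in 9 of 10 cases (adjusted exact p = 0.0082), WRKY 16 (Sotub04g026090) with a log2 fold change of -1.81, against WRKY-b (Sotub05g016650), which rose by 1.85, in the authors' deposited table. At a q threshold of 0.01 the WRKY list of MIJE held 1 higher and 4 lower members (adjusted exact p = 0.16), and under the other 5 alternative settings its call was kept (lowest adjusted exact p = 0.0060). Nitrate reductase (Sotub11g014000) fell from 177.4 to 63.7 FPKM, and 5 of 6 called nitrogen assimilation genes were lower (adjusted exact p = 0.11).

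**Figure D2:**
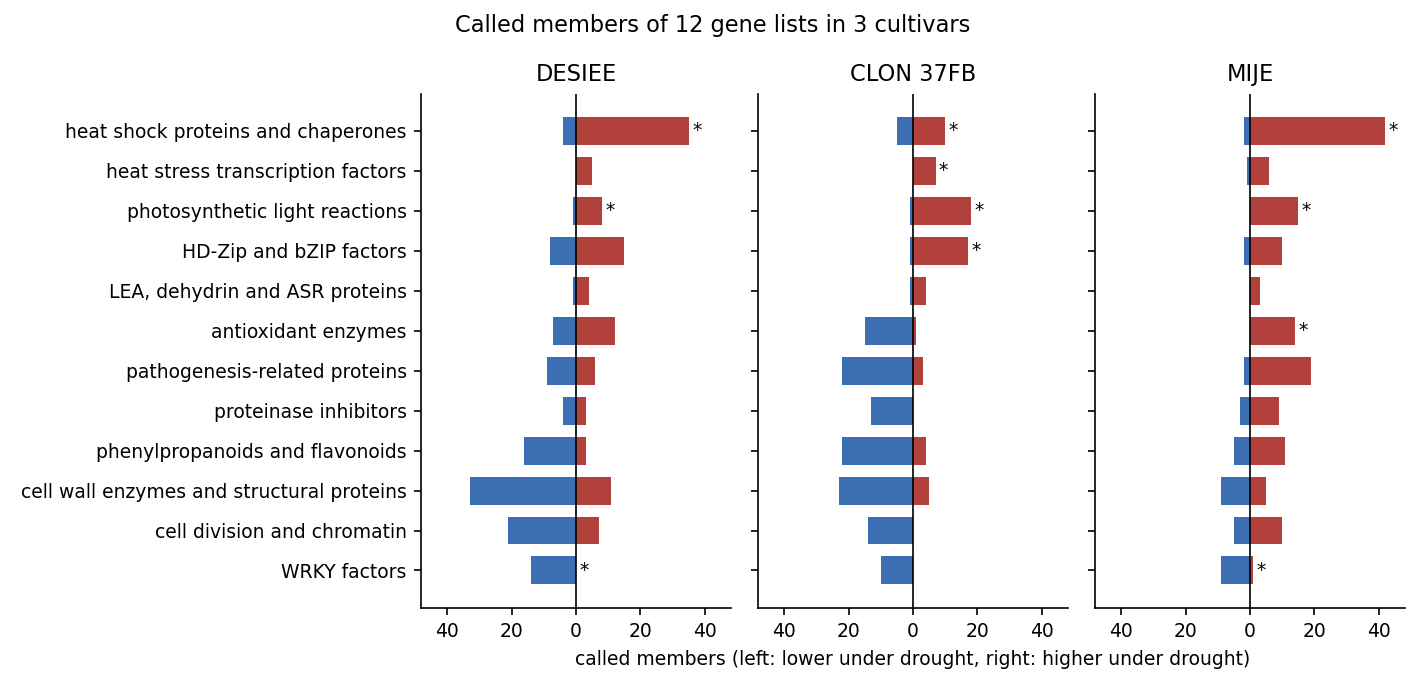
Number of called members (horizontal axis, blue to the left for lower and red to the right for higher under drought) of 12 gene lists (vertical axis) in DESIEE, CLON 37FB and MIJE, with an asterisk where the share of higher members differed from that of the other called genes at adjusted exact p under 0.05. Heat shock proteins rise in 35 of 39 cases in DESIEE and 42 of 44 in MIJE, and pathogenesis-related proteins fall in 22 of 25 cases in CLON 37FB and rise in 19 of 21 in MIJE. The pathogenesis-related list has no asterisk in either of these genotypes (adjusted exact p = 0.20 and 0.062). Of the other called genes 28.5% were higher in CLON 37FB and 63.0% in MIJE.

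Which genes did the genotypes share? In total 3075 genes of the authors' deposited tables were called in at least 1 genotype, 2169 of them in 1, 734 in 2, 168 in 3 and 4 in all 4. DESIEE and CLON 37FB shared 455 genes, of which 430 had the same direction (Fisher's exact test of direction, adjusted p = 2.1e-82). DESIEE and MIJE shared 452 genes, 430 with the same direction (adjusted exact p = 3.3e-98). CLON 37FB and MIJE shared 279 genes, 200 with the same direction and 79 with opposite directions (adjusted exact p = 5.3e-19). Independent lists of these sizes among the loci tested would share about 116, 99.2 and 62.3 genes in the 3 pairs. CARDINAL shared 31 genes with DESIEE, 28 with the same direction (adjusted exact p = 0.00015). It shared 24 with CLON 37FB, 12 with the same direction (adjusted exact p = 1), and 21 with MIJE, 16 with the same direction (adjusted exact p = 0.51). The numbers expected of independent lists were 10.0, 6.32 and 5.41. Each genotype had its own irrigated samples, so no control library was shared between the comparisons. The tests of direction count every gene as independent, which neighbouring copies of a family are not, so their p-values may be too small. They do not measure the spread between samples.

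Of 157 genes called in DESIEE, CLON 37FB and MIJE 135 had one direction, 64 higher and 71 lower, and 1 of the 135 was also called in CARDINAL. TAS14 (Sotub02g027980) rose by a log2 fold change of 2.74 in DESIEE, 3.53 in CLON 37FB and 2.58 in MIJE, and the heat stress factor A-6b (Sotub09g020500) by 1.71, 4.76 and 3.17, in the authors' deposited tables. In the same order the log2 fold changes of the authors' deposited tables were -3.55, -4.06 and -3.94 for peroxidase 1 (Sotub08g017100), -4.47, -2.40 and -3.36 for a cytochrome P450 (Sotub04g019910), and -5.46, -2.31 and -4.04 for the hydroxycinnamoyl transferase Sotub05g025320. Histidine kinase 2, a type of membrane sensor (Sotub04g007630, chromosome 4, 2460663 to 2468278), fell in the same 3 genotypes, with log2 fold changes of -2.54, -1.62 and -2.61, and rose by 2.26 in CARDINAL in the authors' deposited tables. The stay-green 2 gene Sotub12g024750 rose by 5.58 in CARDINAL, 3.40 in DESIEE and 1.81 in MIJE in the authors' deposited tables.

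Which genes differed in their response between genotypes? For genes called in both tables of a pair, the 2 log2 fold changes were compared through the standard errors implied by the authors' test statistics, with adjustment within the pair. These counts hold only for genes called in both, each of which already stands apart from 0 in either genotype, so they mainly restate opposite directions and say little on the size of a shared response. Of 272 genes compared between CLON 37FB and MIJE 75 differed, all of them with opposite directions, and the differences ran from 2.20 to 9.26 on the log2 scale. DESIEE and CLON 37FB differed in 22 of 449 genes, 21 with opposite directions, and DESIEE and MIJE in 9 of 446, all opposite. CARDINAL differed from CLON 37FB in 12 of 24 genes, from MIJE in 7 of 20 and from DESIEE in 3 of 31, with opposite directions in 12, 5 and 3 of them. With standard errors from the deposited p-values instead, DESIEE and MIJE differed in 22 genes.

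Pathogenesis-related proteins and proteinase inhibitors stood out among the genes with opposite directions in CLON 37FB and MIJE. Of 14 pathogenesis-related proteins called in both genotypes 12 were lower in CLON 37FB and higher in MIJE, against 60 of 265 other shared genes (Fisher's exact test, adjusted p = 2.2e-05 over 9 lists). The corresponding count for proteinase inhibitors was 6 of 6, against 66 of 273 (adjusted exact p = 0.0011). Both tests were chosen after the directions had been seen. They also count neighbouring copies of a family as independent genes, and neighbours were not joined here, so these p-values may be too small. PR-1b (Sotub09g006110) fell by 4.80 on the log2 scale in CLON 37FB and rose by 2.28 in MIJE, a difference of -7.08 ± 1.08 (standard error), in the authors' deposited tables. The osmotin-like gene Sotub08g026700 fell by 4.27 in the former and rose by 3.77 in the latter, a difference of -8.04 ± 1.12. For heat shock protein 22 (Sotub05g015330) the difference was -8.25 ± 1.21 and for the beta-1,3-glucanase Sotub04g014510 -8.10 ± 1.18, both computed from the authors' deposited tables. Of 12 heat shock proteins and chaperones called in both 4 were lower in CLON 37FB and higher in MIJE, against 68 of 267 others (adjusted exact p = 0.58). None of the 5 heat stress transcription factors and none of the 8 HD-Zip and bZIP factors called in both genotypes had opposite directions of this kind (adjusted exact p = 0.49 and 0.35). Of the latter 1 had the reverse, a homeobox-leucine zipper gene chosen here after its values were seen (Sotub06g019110), with log2 fold changes of 1.24 in CLON 37FB and -1.33 in MIJE in the authors' deposited tables.

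**Figure D3:**
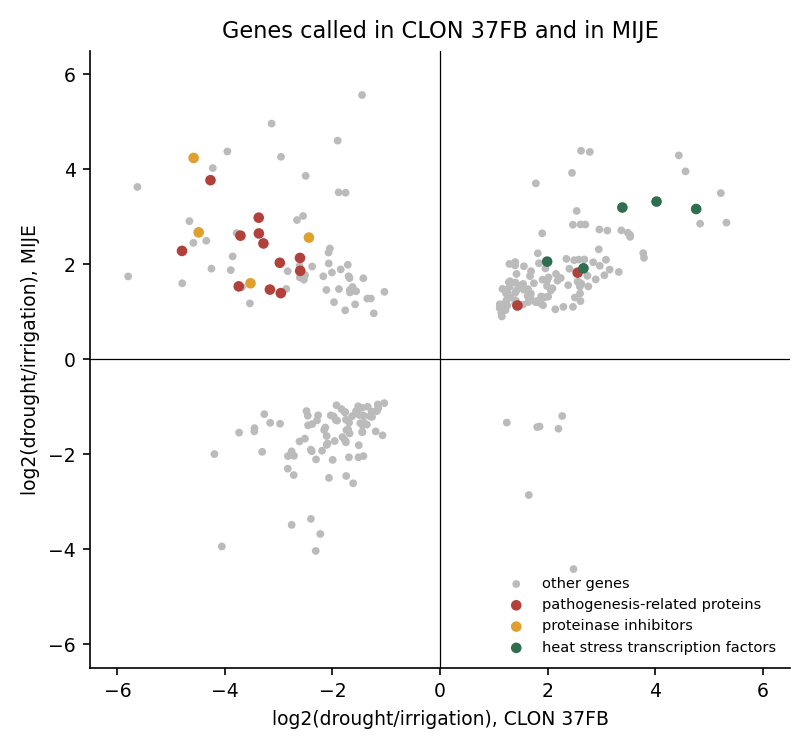
Log2 fold change of drought over irrigation in CLON 37FB (horizontal axis) against MIJE (vertical axis) for genes called in both with values above 0 FPKM throughout, one point per gene, coloured by list. Of the pathogenesis-related proteins 12 lie at the upper left, lower in CLON 37FB and higher in MIJE, while the 5 heat stress transcription factors lie at the upper right.

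PR-1 (Sotub09g006080) was called in all 4 genotypes and not in one direction. Its log2 fold change was -2.97 in CARDINAL, -0.92 in DESIEE, -3.74 in CLON 37FB and 1.54 in MIJE in the authors' deposited tables. For a peptide transporter (Sotub10g016120) it was -5.80 in CLON 37FB, -1.94 in DESIEE, 2.42 in CARDINAL and 1.74 in MIJE in the authors' deposited tables. A cytosol aminopeptidase (Sotub12g007850), of a class induced by wounding, had -3.87 in CARDINAL, -4.35 in CLON 37FB and 2.50 in MIJE in the authors' deposited tables. An aspartic protease inhibitor (Sotub03g015970) had 4.09 in DESIEE, 4.24 in MIJE and -4.58 in CLON 37FB, and beta-carotene hydroxylase (Sotub03g015810) -3.54 in DESIEE, -4.42 in MIJE and 2.48 in CLON 37FB, in the authors' deposited tables. Another beta-carotene hydroxylase gene (Sotub06g016420) rose by 1.85 in DESIEE and 1.30 in MIJE on the log2 scale in the authors' deposited tables.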

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

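In this part the comparisons of the log2 fold changes between genotypes were planned, whereas the tests of explanations were chosen only after the result was seen. Each value below is a difference of log2 fold changes of the authors' deposited tables with an adjusted p under 0.05 within its pair, for a gene called in both genotypes.

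The response differed in 75 genes between CLON 37FB and MIJE. Pathogenesis-related and proteinase inhibitor genes had CLON 37FB minus MIJE differences of -7.08 for PR-1b (Sotub09g006110), -5.28 for PR-1 (Sotub09g006080), -8.04 for an osmotin-like gene (Sotub08g026700) and -8.82 for an aspartic protease inhibitor (Sotub03g015970). Heat shock genes, of which 4 of 12 called in both were lower in CLON 37FB and higher in MIJE, had -8.25 (heat shock protein 22, Sotub05g015330), -5.59 (class I, Sotub06g032320) and -6.51 (class IV, Sotub11g015500). Further differences were -8.10 for a beta-1,3-glucanase (Sotub04g014510), -5.77 for a proline dehydrogenase (Sotub02g033320), -7.02 for a cytochrome P450 (Sotub04g025880), -4.33 for ascorbate peroxidase (Sotub09g006730), -8.33 for a carboxyl methyltransferase (Sotub09g027900), -7.54 for a peptide transporter (Sotub10g016120) and -6.84 for a cytosol aminopeptidase (Sotub12g007850). Beta-carotene hydroxylase (Sotub03g015810) went the other way, with 6.90, as did a homeobox-leucine zipper gene (Sotub06g019110), with 2.57.

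Between DESIEE and CLON 37FB 22 genes differed. DESIEE minus CLON 37FB was 8.67 for the aspartic protease inhibitor Sotub03g015970, 6.77 for the class I heat shock gene Sotub06g032320, 5.69 for heat shock protein 22 (Sotub05g015330) and 5.01 for the beta-1,3-glucanase Sotub04g014510. It was 4.15 for ascorbate peroxidase (Sotub09g006730), 3.75 for chlorophyll a-b binding protein 3C (Sotub03g006060) and 2.82 for PR-1 (Sotub09g006080). Negative differences were -6.02 for beta-carotene hydroxylase (Sotub03g015810) and -3.51 for 9-cis-epoxycarotenoid dioxygenase (Sotub07g025690). Between DESIEE and MIJE 9 genes differed, among them the same dioxygenase gene Sotub07g025690 (-2.55) and the peptide transporter Sotub10g016120 (-3.69), given as DESIEE minus MIJE.

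CARDINAL differed from DESIEE in 3 genes, with CARDINAL minus DESIEE at 4.80 for histidine kinase 2 (Sotub04g007630) and 4.36 for the peptide transporter Sotub10g016120. It differed from CLON 37FB in 12 genes, with 8.22 for the peptide transporter Sotub10g016120, 4.13 for chlorophyll a-b binding protein 3C (Sotub03g006060), 3.87 for histidine kinase 2 (Sotub04g007630) and 3.70 for the cytochrome P450 Sotub04g025880. From MIJE it differed in 7 genes, with 4.87 for histidine kinase 2 (Sotub04g007630), 3.77 for the stay-green 2 gene Sotub12g024750, -3.32 for the cytochrome P450 Sotub04g025880, -4.51 for PR-1 (Sotub09g006080) and -6.37 for the cytosol aminopeptidase Sotub12g007850.

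The first pattern weighed is the set of 72 genes lower under drought in CLON 37FB and higher in MIJE. An exchange of irrigation and drought throughout either table would turn most shared directions against DESIEE, yet 94.5% of the genes shared by CLON 37FB and DESIEE and 95.1% of those shared by MIJE and DESIEE had the same direction. A shift of scale in either table would move the genes of one direction too, but their median difference of log2 change was -0.0018 (quartiles -0.38 and 0.58, 197 genes). Only this median speaks against a shift, and its genes were chosen for a shared direction. For the opposite genes with values above 0 the median was -4.74 (quartiles -6.36 and -3.74, 69 genes). The gap between both medians is largely fixed by the split on direction. Across tables that were normalized separately, irrigated levels of these 69 genes were all higher in CLON 37FB than in MIJE, with a median log2 ratio of 2.85, and drought levels all lower, with a median of -1.97. For each gene the irrigated ratio must exceed the drought ratio, given the choice by direction. The sign of either ratio is not fixed by that choice. Pathogens or pests on some plants could give such a pattern and cannot be told apart from an untested difference between the genotypes themselves: no label records plant health, and the share of the set among shared pathogenesis-related proteins and proteinase inhibitors (90% of 20, against 20.8% of 259 other shared genes) is the observation that prompted this explanation and decides nothing.

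The second pattern is the low number of called genes in CARDINAL. Fewer loci tested cannot account for it, since 18844 were tested in CARDINAL and 19013 to 19490 in the other genotypes. A wider spread between the CARDINAL libraries may contribute: the implied standard errors were 1.20 times those of DESIEE at the median over 31 genes called in both, 0.924 times those of CLON 37FB over 24 and 1.09 times those of MIJE over 20. These ratios rest on called genes, which leaves out the genes a wider spread would hide, so this explanation and an untested weaker response of the genotype cannot be told apart.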

How the results depend on the processing

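The alternatives of this part were planned, except that neighbours counted once and the omission of plastid-type members were chosen only after the result was seen. Of 95 alternatives to counts of genes and lists, overlaps and difference counts, 80 kept the count within 1.5 times and any test on its side of the threshold. Some of these could change little or nothing. The minimum of 1 FPKM removed no call in any genotype, and the minimum log2 fold change of 1 removed none in CARDINAL or CLON 37FB. Leaving out entries with several names removed at most 6 calls per genotype. At a q threshold of 0.01 the calls numbered 0 in CARDINAL, 1062 in DESIEE, 619 in CLON 37FB and 502 in MIJE. Cuffdiff's lowest q in CARDINAL was 0.0135, so no gene there was under 0.01, although all 101 had p of at most 0.00025. The lowest p of the authors' test was 5e-05 in each genotype, and 69.3% of the CARDINAL calls were tied at it. Given that lowest p and the number of ties, no CARDINAL gene could have a q under 0.01. The 0 there therefore does not grade the support of single genes. Shared genes then numbered 0 in the 3 pairs with CARDINAL, 205 for DESIEE and CLON 37FB, 212 for DESIEE and MIJE and 127 for CLON 37FB and MIJE, since fewer genes entered. With an absolute log2 fold change of at least 2 the calls numbered 65, 386, 496 and 258 in CARDINAL, DESIEE, CLON 37FB and MIJE. The drop is by construction, but the order changed too, with the most calls in CLON 37FB and no longer in DESIEE. At this minimum of 2 the share of higher genes went from 55.4% to 49.2% in CARDINAL and from 40.9% to 44.8% in DESIEE. It went from 28.2% to 26.4% in CLON 37FB and from 63.6% to 72.9% in MIJE. Genes listed at 0 in one condition passed this minimum, 21 in CARDINAL, 28 in DESIEE, 41 in CLON 37FB and 30 in MIJE. Of those 21 in CARDINAL 16 were at 0 under drought and so counted as lower, and the 49.2% there depends on them. In CARDINAL the share was 63.4% with at least 5 FPKM. It was 63.75% without genes listed at 0, because most of the genes left out were lower. The causes of the other shifts were not tested. Standard errors from the deposited p-value were the smaller in most called genes of each genotype. They raised the genes that differed between DESIEE and MIJE from 9 to 22, all 9 among them. Of 12 list calls 6 were kept at q of 0.01, 7 with each distinct description counted once (4 were lost, and heat stress factors in CLON 37FB had fewer than 5 distinct descriptions and were not tested), 9 with neighbours within 200 kb counted once, 10 with an absolute log2 fold change of at least 1, 11 without plastid-type members and 12 with at least 5 FPKM. The lists called under none of the main settings but under one alternative were HD-Zip and bZIP factors and dividing tissue in DESIEE and pathogenesis-related proteins in MIJE (adjusted exact p = 0.044 each, q of 0.01), and phenylpropanoids in DESIEE (0.046, distinct descriptions). No paired analysis was possible because the tables hold 1 pooled value per condition. For the same reason the planned replicate block, leave-one-out, smaller pseudocount of 0.1 and other models per sample were not run, nor were other splits of the samples. Depth is unknown, so its limits could not be assessed.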

Other observations

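The tests of this part compare gene lists that were fixed before the data were examined, except that the comparison of CLON 37FB with the other cultivars was designed after the pattern it concerns had been seen, with its prediction written before its result. None of the hormone and clock lists had an adjusted p under 0.05 by Fisher's exact test. Clock and flowering genes were higher in 5 of 7 cases in DESIEE, 5 of 8 in CLON 37FB and 6 of 9 in MIJE (adjusted exact p = 0.29, 0.15 and 1). A CONSTANS-like zinc finger gene, of a family that acts in photoperiodic flowering (Sotub07g020650), had log2 fold changes of 3.49 in CLON 37FB and 2.67 in MIJE in the authors' deposited tables. Auxin response genes were lower in 13 of 18 cases in DESIEE, 9 of 12 in CLON 37FB and 8 of 15 in MIJE (adjusted exact p = 0.57, 1 and 0.37). Gibberellin and cytokinin genes were lower in 13 of 17 cases in DESIEE, 10 of 14 in CLON 37FB and 4 of 8 in MIJE (adjusted exact p = 0.41, 1 and 0.66). Gibberellin 20-oxidase 2, an enzyme of gibberellin synthesis (Sotub06g009210), fell from 10.4 to 1.03 FPKM in DESIEE in the authors' deposited table. Genes of abscisic acid synthesis, breakdown and signalling divided in DESIEE into 5 higher and 5 lower, in CLON 37FB into 5 and 3, and in MIJE into 4 and 4 (adjusted exact p = 0.92, 0.15 and 0.66). The receptor gene PYL6 (Sotub06g011190) fell in DESIEE from 28.3 to 6.03 FPKM in the authors' deposited table. Jasmonate genes were higher in 5 of 6 cases in MIJE and 1 of 5 in DESIEE (adjusted exact p = 0.65 and 0.83), and the 3 called in CLON 37FB were lower. Ethylene genes were higher in 6 of 10 cases in DESIEE, 1 of 8 in CLON 37FB and 4 of 7 in MIJE (adjusted exact p = 0.57, 0.66 and 0.89).

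Water channels and proline genes were called in small numbers. Aquaporins were lower in 4 of 6 cases in DESIEE and 2 of 5 in MIJE (adjusted exact p = 1 for both), and in 3 of 4 in CLON 37FB. An abundant aquaporin-like gene (Sotub06g030840) went from 900.1 to 191.5 FPKM in DESIEE in the authors' deposited table. A proline dehydrogenase gene, whose product breaks down the osmolyte proline (Sotub02g033310), had log2 fold changes of -1.40 in DESIEE, -1.17 in CLON 37FB and -1.09 in MIJE in the authors' deposited tables. A neighbouring proline dehydrogenase gene (Sotub02g033320) went opposite ways, with -3.89 in CLON 37FB and 1.88 in MIJE in the authors' deposited tables. Secreted peroxidases were lower in 5 of 5 cases in DESIEE and 8 of 8 in CLON 37FB (adjusted exact p = 0.22 and 0.27), and in 2 of 4 in MIJE. Ethylene response and DREB factors were lower in 11 of 18 cases in DESIEE, 6 of 8 in CLON 37FB and 5 of 7 in MIJE (adjusted exact p = 1, 1 and 0.26). The NAC factor Sotub02g009520 had log2 fold changes of -2.69 in DESIEE, -2.31 in CLON 37FB and -2.11 in MIJE in the authors' deposited tables, within a list of 3 higher and 7 lower calls in DESIEE (adjusted exact p = 0.75). Cysteine proteases and senescence genes were higher in 4 of 10 cases in DESIEE, 1 of 8 in CLON 37FB and 6 of 7 in MIJE (adjusted exact p = 1, 0.66 and 0.65). Protochlorophyllide reductase, an enzyme of chlorophyll synthesis (Sotub12g005670), rose by 1.66 in CARDINAL, 1.46 in DESIEE and 1.08 in MIJE on the log2 scale in the authors' deposited tables.

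Markers of tissue other than leaf, and of trichomes and guard cells within the leaf, were rare among the called genes. Tuber and storage proteins were lower in 4 of 5 cases in DESIEE (adjusted exact p = 0.83), 4 of 4 in CLON 37FB and 1 of 1 in MIJE. A patatin gene, of the main storage protein family of the tuber (Sotub08g006500), went from 282.6 to 93.3 FPKM in CLON 37FB in the authors' deposited table. Vascular and root markers had 1 called gene each in DESIEE, CLON 37FB and MIJE, and that of DESIEE was higher. In CLON 37FB and MIJE it was the same phloem lectin gene (Sotub02g015240), with log2 fold changes of -2.07 and 2.02. It is thus among the genes lower under drought in CLON 37FB and higher in MIJE. Trichome markers had 1 called gene in MIJE, and guard cell markers 1 in DESIEE. Which cells carried these transcripts was not tested.

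A hypothesis tested here was that CLON 37FB, and not MIJE, stood apart in the genes that were lower under drought in the former and higher in the latter. If so, the same genes would be mostly higher in DESIEE and CARDINAL. Of the 72 genes 16 were called in DESIEE, 10 higher and 6 lower, and 4 in CARDINAL, 2 higher and 2 lower. These 12 of 20 higher calls come from 17 distinct genes, so they are not independent of each other. Within DESIEE alone, where each gene counts once, the division did not differ from an even one (two-sided exact binomial test, p = 0.45), so the tables leave open which of both genotypes departed from the others.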
